A study of Mus musculus with 7 samples.

How the data were processed

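The data are bulk RNA-seq of GFP-positive cells sorted from mouse spleen, 4 libraries from mice without ligature (health) and 3 from mice with ligature-induced periodontitis. Per the labels' protocols, RNA was extracted with TRIzol and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, the build was mm10 and the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2; the notes give no role, order or settings for them. The strand setting, read length and annotation release are not given in the sources used here. Strand use is not stated, so reads of overlapping genes on opposite strands cannot be told apart.

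The authors deposited a table of FPKM values for 54532 genes, with 1 column per library and columns for gene length, position and biotype. Of these genes 54495 matched a GENCODE M21 gene (GRCm38) by identifier, and 53585 of those, or 98.3%, had the same chromosome, start and end. Gene names come from the deposited table. It holds 105 entries whose name another entry already has; where a name occurs more than once, the entry with the highest mean was used. Multiplied by gene length, 100% of the nonzero values of each library are whole multiples of 1 step within 0.001 of a read, so the number of reads behind each value is known. Recovered reads totalled 17891393, 16209272, 15101043 and 14161438 in health 1 to 4 and 16717942, 14991990 and 13513806 in periodontitis 2 to 4. The library total that the deposited FPKM was divided by is not the sum of these reads: the ratio ran from 0.889 to 1.12. At these depths 1 read in a gene 1 kilobase long is worth 0.0594 to 0.0705 FPKM. FPKM columns do not share a total: they sum to between 375857 and 379328 in health and to 568848, 475268 and 526989 in periodontitis 2, 3 and 4. The 57-base feature Gm23935 alone had 162726 FPKM in periodontitis 3 and 873 FPKM in periodontitis 2. Features under 200 bases made up 1.40%, 36.7% and 24.2% of the FPKM total of periodontitis 2, 3 and 4, and 3.31% to 9.63% of that of the health libraries, but at most 1.13% of the recovered reads of any library. Rescaling to a fixed total lowers the periodontitis libraries against health, periodontitis 2 the most.

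Groups and library numbers come from the library names in the sample descriptions. The numbers in the sample titles differ from these in periodontitis, where title 1 is library 2, title 2 library 3 and title 3 library 4. Equal numbers were not treated as pairs. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom of recovered reads over any pair was 27.3.

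Computed here, with R 4.3.3 and limma 3.58.1: genes with a mean of at least 1 FPKM over the 7 libraries were tested on log2(FPKM + 1) with empirical Bayes moderation and a trend in the variance. Adjusted p-values are Benjamini-Hochberg values over the 12999 genes tested, two-sided, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A count test was not the main one because the deposited unit is FPKM, and limma voom on the recovered reads was run as an alternative. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Mean list scores per library were compared by an exact permutation test over the 35 splits of 4 against 3, whose smallest two-sided p is 0.0571. A ratio of genes per library carries a 95% interval from the pooled SD of both groups. Where a group has 0 reads, a fold is a lower bound against 3 reads over the libraries of that group. Bounds and floors cover counting error only.

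The 34 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover Th17 programs, T cell receptor signalling, T cell states, other spleen cell types, the cell cycle, interferon responses, metabolism, ribosomal and mitochondrial genes and stress. The 21 lists described in full were picked from them after values were seen, which left 122 results tested for an outlying library in place of 171. The rule names Zap70, Il17a, Il17f, Il23a, Il23r and Csf2; the 10 protein-coding genes with the largest rise and the 10 with the largest fall past the threshold whose groups do not overlap, leaving out predicted genes and antigen receptor segments; and from each list described up to 4 members with the smallest unadjusted p, and every member past the threshold where there are at most 6. Other members named beside a list, the CD3 subunits, Xist, the other Y-linked genes and Gm23935 were chosen after their values were seen.

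The fit was tested on simulated data: reads drawn for the real genes from the real means and library totals at a dispersion of 0.0811, with 200 genes changed. In all, 12857 genes were run for periodontitis against health. Of these, 96 of 99 genes with a 4-fold change and 22 of 100 with a 2-fold change were recovered. The calls also took in 13 unchanged genes, a larger share than the adjusted p threshold allows on average. The same dispersion was used for both groups. The real libraries correlated at 0.912 to 0.932 within health and at 0.809 to 0.885 within periodontitis. The share of false calls under such unequal spread was not tested. Camera gave p under the threshold for 2 of 100 random lists. The simulated genes were drawn independently, so this does not test camera on lists whose members move together. In the real lists the estimated correlation reached 0.913, for ribosomal protein genes. The changed genes were drawn from those with a mean of at least 100 reads. Even there a 2-fold change was missed more often than found.

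The alternatives fixed with the tests were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, rescaling each library to a total of 1000000 (TPM), median-of-ratios scaling, quantile normalization, removal of hemoglobin, immunoglobulin and mitochondrial genes with each library rescaled to its former total, 3 other settings of the moderation and weights, protein-coding genes only, a replicate block in 2 versions, voom, and leaving out each library in turn. Added after the data were seen were a scale relative to the CD3 subunit genes, kept to the study's own genes after its result over all genes was seen, omission of X and Y genes, omission of features under 200 bases with each library rescaled to its former total, and omission of health 1 and periodontitis 2 together. Ranges of adjusted p over the settings leave out the replicate block and, for single genes, the scale relative to the CD3 genes. Those of lists take in camera with an estimated correlation and also fry, which tests against no change and not against other genes. The ratios to CD3 genes and of receptor chains without each library were also added after the data were seen. The planned correlation of Zap70 and Il17a was not computed, since the libraries form separate groups.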

Results

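RNA was sequenced from spleen cells of IL-17-GFP reporter mice, sorted by flow cytometry for GFP, the fluorescent protein that reports the IL-17 locus in these mice. The sorted cells are labelled as Th17 cells, the T helper cells that make IL-17. In the periodontitis group silk ligatures had been tied around the lower first molars of both sides, which sets off inflammation of the gum and loss of the bone that holds the teeth. The health group had no ligature. There were 4 health libraries, numbered 1 to 4, and 3 periodontitis libraries, numbered 2 to 4 after their library names. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries. Values are FPKM, fragments scaled to gene length and library total. The values of each library come in whole reads, and the reads recovered from them totalled 14161438 to 17891393 in the health libraries and 13513806 to 16717942 in the periodontitis libraries. Between 16852 and 19721 genes had a read in the health libraries. In periodontitis libraries 2, 3 and 4 these were 15322, 17546 and 12226 genes. Means below are given ± SD over n = 4 health and n = 3 periodontitis libraries.

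The comparison asks how the sorted spleen cells of mice with periodontitis differ in gene expression from those of mice without it, with attention to Zap70, a kinase that binds the T cell receptor complex and passes on its signal. The lists of Th17, gamma-delta T cell and, in part, T cell receptor genes were higher in periodontitis, and that of macrophage genes was lower. With an estimated correlation their adjusted p was 0.0419, 0.0757, 0.145 and 0.145 in that order. Sex-linked genes had a female pattern in all 4 health libraries and a male one in all 3 periodontitis libraries. Sex and periodontitis therefore cannot be told apart for any gene below. The sorted cells of the health group also held little Il17a, with 94 reads over the 4 libraries. The largest rises among protein-coding genes with established names were those of the cytokines Il17a and Il17f, the surface receptor Cd163l1, the chemokine receptor Cxcr6 and the inhibitory receptor Ctla4. The largest falls among them were those of Adap2, Cd163, Cox6a2, Mertk and Mrc1. Cd163, Mertk and Mrc1 are scavenger and clearance receptors of macrophages. Of 12999 genes tested, 732 were higher and 1321 lower in periodontitis at an adjusted p under 0.05 (limma on log2(FPKM + 1), two-sided, Benjamini-Hochberg adjustment). Of the 2053 genes called, 2040 had groups whose library values did not overlap. That was so for 29.8% of the genes tested, where chance gives 5.71%. The counts moved with single libraries: 484 genes were higher without health 1, 445 without health 2 and 482 without health 3, and 871 were lower without health 2. Rescaling each library to the same total gave 415 higher and 2692 lower, so that 13.4% of calls were higher in place of 35.7%; it moved the median log2 change of all genes by -0.47, and quantile normalization moved it by 0.12. Leaving out features under 200 bases and rescaling each library to its former total, chosen together after the data were seen, gave 1428 higher and 973 lower, or 59.5% higher, with a median moved by 0.24.

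**Figure D1:**
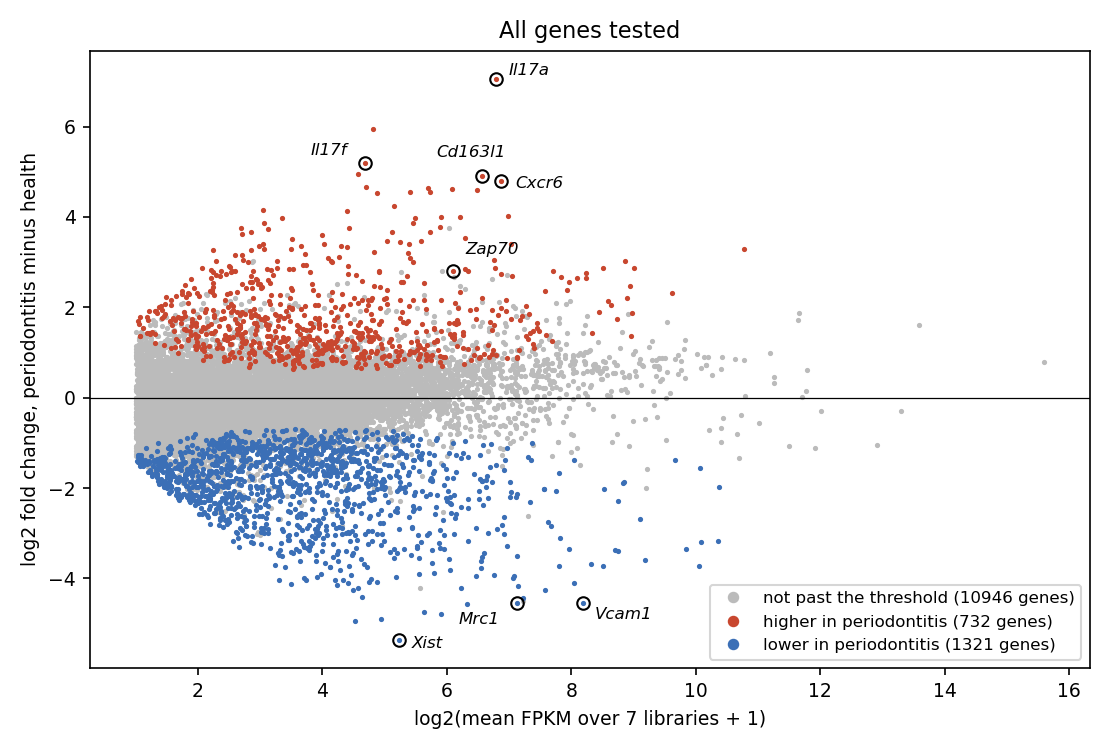
Log2 fold change of each of the 12999 genes tested (vertical axis, periodontitis minus health on the log2(FPKM + 1) scale) against its mean level over the 7 libraries (horizontal axis, log2). Red points are the 732 genes higher and blue points the 1321 genes lower in periodontitis at an adjusted p under 0.05, grey points the rest; circled genes are named.

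Zap70 was higher in each of the 3 periodontitis libraries than in any health library. It lies on chromosome 1 at 36761798 to 36782818 on the plus strand (mm10). Its level was 18.6 ± 5.15 FPKM in health and 132 ± 14.1 FPKM in periodontitis, a 7.09-fold difference of the means. The log2 fold change was 2.80 (SE 0.26, 95% interval 2.20 to 3.40; adjusted p = 0.000674). Of the 4 tested genes that the study's description names, 3 were higher, and 4 were so when adjusted over the list alone, where the adjusted p of Zap70 was 4.76e-06. The list passed (camera adjusted p = 1.36e-05), with an adjusted p of 0.0600 with an estimated correlation. The study named these genes with the same samples in hand, so the list is not independent evidence of its direction. The 4 subunits of the CD3 complex, through which the T cell receptor signals and to which Zap70 binds, were higher by like amounts. Their log2 fold changes were 2.21 for Cd3d (SE 0.57), 2.69 for Cd3e (SE 0.41), 2.81 for Cd3g (SE 0.42) and 2.47 for Cd247 (SE 0.25). The levels of Cd3d and Cd3g were uneven, and highest in periodontitis 2. Cd3d was 339, 99.0 and 87.4 FPKM in periodontitis 2, 3 and 4, and Cd3g 260, 109 and 109 FPKM. In health 1 Cd3d was 12.6 FPKM, against 37.2 to 41.8 FPKM in the other health libraries. Measured against the mean of these 4 genes in each library, a scale chosen after the data were seen, Zap70 differed by 0.25 on the log2 scale (95% interval -0.37 to 0.88; exact permutation p = 0.400, two-sided); without periodontitis 2, 3 or 4 the difference was 0.49, 0.15 or 0.12. Its adjusted p was 0.656 on that scale and ranged from 0.000146 to 0.00526 over 23 other settings, those with a replicate block left out as in every range given here.

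Il17a (chromosome 1, 20730905 to 20734496, plus strand) was the protein-coding gene with the largest rise. It stood at 3.76, 0, 1.13 and 0 FPKM in health 1 to 4 and at 362, 269 and 136 FPKM in periodontitis 2 to 4. The log2 fold change was 7.06 (SE 0.58; adjusted p = 0.000543). Il17f, its neighbour on chromosome 1 (20777146 to 20790617, minus strand), was 0.177 ± 0.224 FPKM in health and 57.2 ± 45.7 FPKM in periodontitis (log2 fold change 5.19; limma adjusted p = 0.00130). Il23r, the receptor for the cytokine that maintains Th17 cells, lies on chromosome 6 (67422932 to 67491855, minus strand) and was 0.345 ± 0.260 and 20.9 ± 9.41 FPKM (log2 fold change 3.96; limma adjusted p = 0.000543). Csf2, which encodes the cytokine GM-CSF (chromosome 11, 54247271 to 54249667, minus strand), had no read in any health library and 11.1, 5.50 and 0 FPKM in periodontitis 2, 3 and 4. The mean in periodontitis was at least 94.4-fold higher than the level of 3 reads over the health libraries, a bound that covers counting error only. Its limma adjusted p was 0.104 with all libraries and 0.00256 without periodontitis 4, was 0.0324 with quantile normalization and 0.0354 with library weights, and ranged from 0.00256 to 0.381 over the settings of all genes. Il23a (chromosome 10, 128296139 to 128298752, minus strand) stayed at or below 0.121 FPKM in every library, with 7 reads in health and 4 in periodontitis together, so no difference was detectable at this depth. The libraries formed separate groups in Zap70 and in Il17a, so no correlation between them is given over the 7, and groups of 4 and 3 are too small for one within a group.

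**Figure D2:**
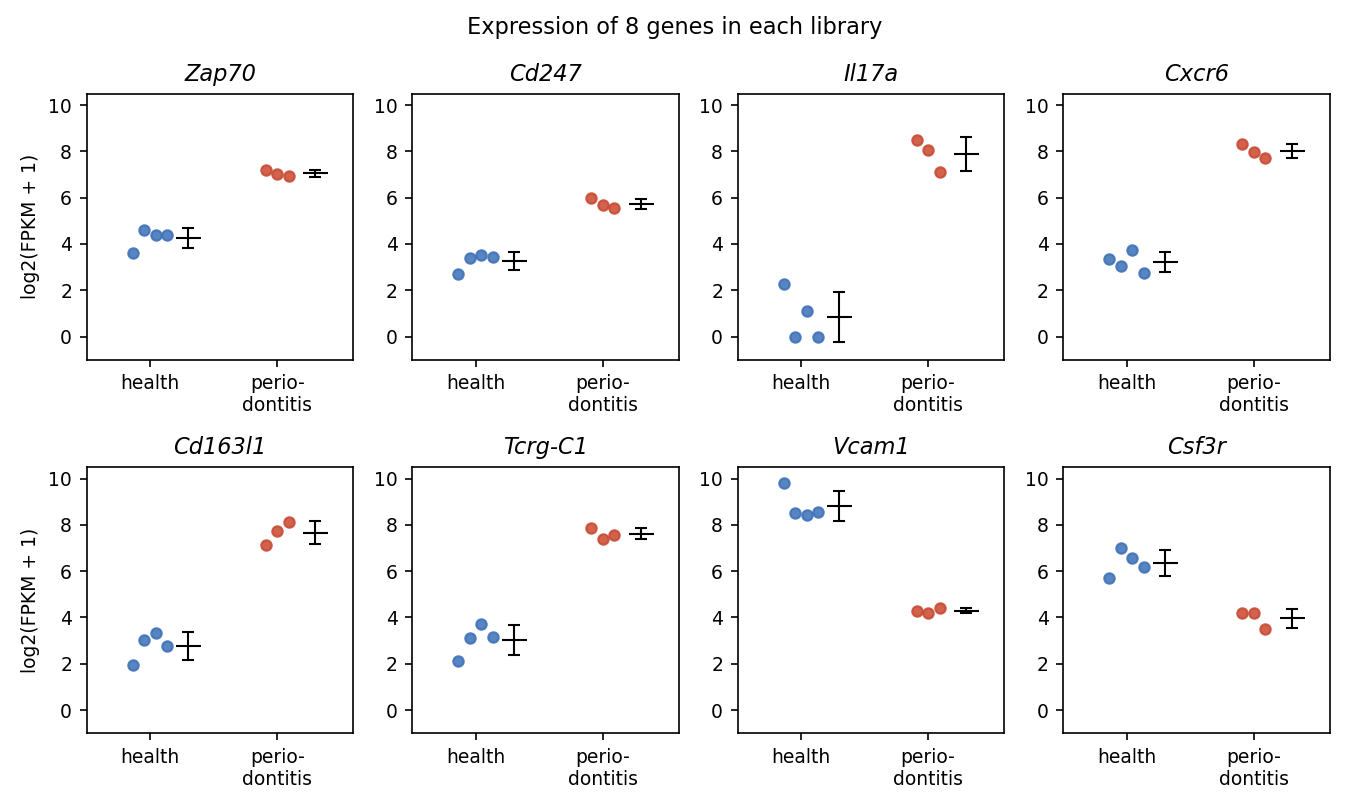
Expression of 8 genes in each library as log2(FPKM + 1) (vertical axes), with health libraries 1 to 4 in blue and periodontitis libraries 2 to 4 in red, in that order from left to right; black marks give each group's mean with SD. Zap70, Cd247, Il17a, Cxcr6, Cd163l1 and Tcrg-C1 are higher in all 3 periodontitis libraries than in any health library, Vcam1 and Csf3r lower.

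Genes that define Th17 cells were higher in periodontitis. Of 20 tested members of the Th17 list, 14 were higher, 1 was lower and 5 did not pass. Tmem176a was 7.18 ± 2.63 FPKM in health and 128 ± 36.1 FPKM in periodontitis. Il17re was higher by 3.28 on the log2 scale and Ccr6, the chemokine receptor of Th17 cells, by 2.18. Il6ra, a receptor chain for IL-6, was the member that was lower, at 23.6 FPKM in health and 7.44 in periodontitis. Adjusted over the list alone, the counts were 14 higher and 1 lower. The mean log2 change of the list was 2.29, where the 4 CD3 subunit genes changed by 2.21 to 2.81 in the same libraries. Here and below, a list set beside the CD3 genes gives no change per T cell. The RNA that other cells add to each list was not measured. The list as a whole was higher than other genes (limma camera, preset correlation 0.01, adjusted p = 7.43e-11), and remained so with an estimated correlation (adjusted p = 0.0419).

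Of 19 tested members of the pathogenic Th17 list, which holds genes reported for tissue-damaging Th17 cells, 8 were higher and 11 did not pass. Il18r1 was higher by 2.99 on the log2 scale, Icos by 2.57, Bhlhe40 by 2.17 and Ifng by 2.86. Lag3, Lgals3 and Casp1 did not pass, with log2 values of -0.79, -0.53 and -0.22. Adjusted over the list alone, 11 were higher. The mean log2 change was 1.48 for this list and 2.0 for the cytokine and chemokine genes below, beside 2.21 to 2.81 for the CD3 genes. The camera adjusted p was 8.62e-07, and the adjusted p was 0.136 with an estimated correlation. Of 19 tested cytokine and chemokine genes of T cells, 10 were higher, 11 when adjusted over the list alone, and none was lower. Areg, an epithelial growth factor, was 0.114 ± 0.161 FPKM in health and 12.7 ± 2.47 FPKM in periodontitis. Il22, which acts on epithelial cells, was 0.176 ± 0.252 and 8.21 ± 5.12 FPKM. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, was higher by 2.60 on the log2 scale. The list passed (camera adjusted p = 2.35e-08), with an adjusted p of 0.168 with an estimated correlation.

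Genes of gamma-delta T cells were higher, with the largest mean log2 change, 3.53, among the lists of other cell types. Of the 12 tested members, 11 were higher and all 12 were so when adjusted over the list alone, with a median log2 fold change of 3.59. The receptor segments Tcrg-V6 and Trdv4 were 0.821 ± 0.691 and 3.57 ± 0.945 FPKM in health and 52.2 ± 8.05 and 113 ± 23.0 FPKM in periodontitis (log2 fold changes 4.94 and 4.65). The constant segments Tcrg-C1 and Trdc were higher by 4.59 and 3.75 on the log2 scale. Cd163l1, a scavenger-receptor family gene that marks a subset of gamma-delta T cells, was 6.21 ± 2.61 and 210 ± 71.2 FPKM (log2 fold change 4.90; limma adjusted p = 0.000448). Sox13, a transcription factor of IL-17-producing gamma-delta T cells, was higher by 3.51. The gamma constant segments are near-identical to one another, so reads may be split between them. The list passed (camera adjusted p = 4.23e-14), and its adjusted p was 0.0757 with an estimated correlation. In the same libraries the CD3 subunit genes changed by 2.21 to 2.81 on the log2 scale. The alpha-beta chain genes Trac and Trbc1 changed by 2.64 and 2.37.

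Genes of the T cell receptor and its first signalling steps were higher in part. Of 39 tested members, 21 were higher, 1 was lower and 17 did not pass; adjusted over the list alone, 25 were higher and 5 lower. Cd4, the co-receptor of helper T cells, was 28.0 ± 0.930 FPKM in health and 124 ± 17.9 FPKM in periodontitis (log2 fold change 2.10). Sit1, an adaptor at the T cell membrane, was higher by 3.09 on the log2 scale and Cd247 by 2.47. The chains of the alpha-beta receptor, Trac and Trbc1, were higher by 2.64 and 2.37. Ptpn6, a phosphatase of many blood cell types, was the member that was lower, by -1.01. The list passed (camera adjusted p = 1.19e-09), with an adjusted p of 0.145 with an estimated correlation. Of 25 genes induced early after receptor stimulation, 11 were higher and none lower, or 15 and 1 when adjusted over the list alone. The mean log2 change of the list was 1.04, where the 4 CD3 subunit genes, markers of T cells, changed by 2.21 to 2.81 in the same libraries. How much of the list's RNA came from cells other than T cells was not measured. The lower value is therefore no measure of the early response per T cell. Dusp5 was higher by 3.21 on the log2 scale, Tnfaip3 by 2.57, Nfkbia by 1.36 and Junb by 1.75. Egr2 and Egr3, also induced by the receptor, had log2 values of 0.28 and 0.16 and did not pass. The camera adjusted p of the list was 8.78e-08, and 0.136 was its adjusted p with an estimated correlation.

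Genes of effector memory T cells were higher in part. Of 16 tested members, 8 were higher and none lower; adjusted over the list alone, 12 were higher and 1 lower. The mean log2 change was 1.64 for this list and 1.54 and 1.38 for those of regulatory and follicular helper T cells, beside 2.21 to 2.81 for the CD3 genes in the same libraries. These values give no change per T cell either, since RNA of other cells in the lists was not measured. Cxcr6 was 8.62 ± 2.89 FPKM in health and 259 ± 55.3 FPKM in periodontitis (log2 fold change 4.78; limma adjusted p = 0.000123). Itgae, an integrin chain of tissue T cells, was higher by 2.37 on the log2 scale and Ccr2 by 2.16. The list passed with the preset correlation (camera adjusted p = 8.80e-08) and with an estimated one (adjusted p = 0.0419). The list of naive and central memory T cells did not pass (camera adjusted p = 0.459). Of its 14 members 1 was lower, the actin crosslinker Actn1 (log2 fold change -2.67), and 2 were higher, the egress receptor S1pr1 and the IL-7 receptor chain Il7r, or 3 over the list alone. The call of S1pr1 was lost without health 2 or periodontitis 2 or 4 (adjusted p = 0.0542, 0.0669 and 0.0571; range over the settings 0.00783 to 0.0697). That of Il7r was lost without health 2 or 3 or periodontitis 2, 3 or 4 (adjusted p = 0.0687, 0.0638, 0.0713, 0.0793 and 0.0686; range 0.0141 to 0.0793). Among genes of regulatory T cells 4 of 8 were higher, Ctla4 by 4.62, Capg by 2.15, Ikzf2 by 1.53 and Il2ra by 1.48, with the same count over the list alone. Foxp3, the transcription factor that defines these cells, was 1.56 FPKM in health and 1.99 in periodontitis and did not pass (adjusted p = 0.621). The regulatory list passed (camera adjusted p = 0.000115), with an adjusted p of 0.145 with an estimated correlation. Of 7 follicular helper genes, 4 were higher and 1 lower, or 5 and 1 over the list alone (camera adjusted p = 0.00302; adjusted p = 0.182 with an estimated correlation). Pdcd1, which encodes PD-1, was higher by 3.40 on the log2 scale and Icos by 2.57. Bcl6, the transcription factor of follicular helper cells, was the lower one at -1.24, a call lost without health 1, 2 or 3 or periodontitis 4 (adjusted p = 0.0571, 0.0670, 0.0687 and 0.0570; range 0.00708 to 0.0711).

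Genes of macrophages were lower in periodontitis. Of 17 tested members of the monocyte and macrophage list, 15 were lower, 1 was higher and 1 did not pass, with the same counts when adjusted over the list alone and a median log2 fold change of -3.35. Vcam1, an adhesion molecule of red pulp macrophages, was 492 ± 261 FPKM in health and 18.6 ± 1.44 FPKM in periodontitis (log2 fold change -4.54; limma adjusted p = 0.000448). The iron exporter Slc40a1 was 238 ± 112 and 11.5 ± 2.76 FPKM, and Adgre1, which encodes the macrophage marker F4/80, 225 ± 131 and 12.3 ± 1.03 FPKM. Ccr2, also carried by effector T cells, was the member that was higher. Lyz2 did not pass (log2 value -0.68). The list was lower as a whole (camera adjusted p = 1.05e-10), with an adjusted p of 0.145 with an estimated correlation. Of the 10 largest falls, Mrc1 went from 236 ± 135 to 8.27 ± 0.593 FPKM, Mertk from 136 ± 71.6 to 4.37 ± 1.34 and the integrin chain Itgad from 253 ± 157 to 9.83 ± 3.44. Adap2, Cd163 and Cox6a2 had log2 fold changes of -4.90, -4.79 and -4.74, and Sdc3, Galnt3 and Tmem26 of -4.26, -4.40 and -4.22. Cox6a2 lies within the span of Itgad on the opposite strand. Since strand use is not stated, reads counted for Cox6a2 may come from Itgad. Health 1 stood above the other health libraries in this list, with a mean score of 8.62 against 7.60 to 7.91.

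Genes of neutrophils and dendritic cells were lower as lists. Of 17 neutrophil genes 8 were lower and none higher, over all genes and over the list alone. Csf3r, the receptor for the neutrophil growth factor G-CSF, fell from 86.1 ± 32.7 to 14.9 ± 4.03 FPKM, and Cxcr2 from 44.5 ± 17.9 to 9.71 ± 1.91 FPKM. The granule genes Mpo, Mmp8, Mmp9 and Ltf were lower by log2 values of -1.58, -1.54, -1.53 and -1.39. Camp and Ngp, also of the granules, and the alarmin genes S100a8 and S100a9 did not pass. The neutrophil list passed (camera adjusted p = 1.56e-05; adjusted p = 0.315 with an estimated correlation). Of 10 dendritic cell genes 4 were lower, or 5 over the list alone, among them Itgax by -1.74 and Clec9a by -1.66 on the log2 scale. The dendritic list passed (camera adjusted p = 0.0133; adjusted p = 0.182 with an estimated correlation), and did not after rescaling to one total per library (adjusted p = 0.0627; range 0.00257 to 0.182).

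B cell genes as a list did not pass (camera adjusted p = 0.513), although without health 1 the list was lower (camera adjusted p = 0.0145; range 0.0145 to 0.899 over the settings). Of its 18 members Bank1 alone was past the threshold, at 23.5 ± 3.37 FPKM in health and 7.80 ± 2.18 FPKM in periodontitis. Plasma cell genes were higher as a list: 3 of 11 passed over all genes, Sdc1, Irf4 and Ighg1, and 8 over the list alone (camera adjusted p = 5.91e-05; adjusted p = 0.204 with an estimated correlation). Sdc1, the syndecan on plasma cells, was higher by 1.72 on the log2 scale. The call of Ighg1 was lost without any of health 2, 3 and 4 and periodontitis 2, 3 and 4 (adjusted p = 0.0993, 0.0946, 0.114, 0.117, 0.0523 and 0.117; range 0.0122 to 0.117), and that of Irf4 without health 1, 2 or 3 or periodontitis 3 or 4 (adjusted p = 0.0972, 0.105, 0.103, 0.0941 and 0.101; range 0.0277 to 0.218). Jchain, the joining chain of secreted antibodies, was 362 ± 121 FPKM in health and 1258 ± 724 FPKM in periodontitis (limma adjusted p = 0.0560, and 0.0169 without periodontitis 3; range 0.0103 to 0.191 over the settings). Immunoglobulin genes took 1.27% to 2.07% of the recovered reads of a health library and 4.07%, 2.34% and 7.04% of those of periodontitis 2, 3 and 4. Erythroid genes were higher as a list, with 4 of 14 members higher, 1 lower and 9 not past the threshold, or 6 and 1 over the list alone (camera adjusted p = 0.000379; adjusted p = 0.249 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells, was higher by 1.72 on the log2 scale and Slc4a1, the anion exchanger of the red cell membrane, by 1.33. The call of Slc4a1 was lost with libraries rescaled to the same total and with library weights (limma adjusted p = 0.0633 and 0.0512, range 0.00667 to 0.0633). Car2, Hbb-bt and the lower Epor, the erythropoietin receptor, passed with all libraries. The call of Car2 was lost without any 1 library except periodontitis 3 (adjusted p from 0.0564 without health 1 to 0.0930 without health 3; 0.0712, 0.0781, 0.0810 and 0.0871 without health 2, health 4, periodontitis 2 and periodontitis 4; range 0.00489 to 0.119). That of Hbb-bt was lost without the same libraries (0.112, 0.109, 0.0676 and 0.101 without health 1 to 4, 0.0881 and 0.0972 without periodontitis 2 and 4; range 0.00619 to 0.146). That of Epor was lost without health 1, 2 or 3 or periodontitis 3 or 4 (adjusted p = 0.0614, 0.0853, 0.0633, 0.0998 and 0.0627; range 0.00919 to 0.0998). Hemoglobin genes took 0.165% to 0.335% of the recovered reads of a health library and 1.21%, 0.468% and 0.762% of those of periodontitis 2, 3 and 4.

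**Figure D3:**
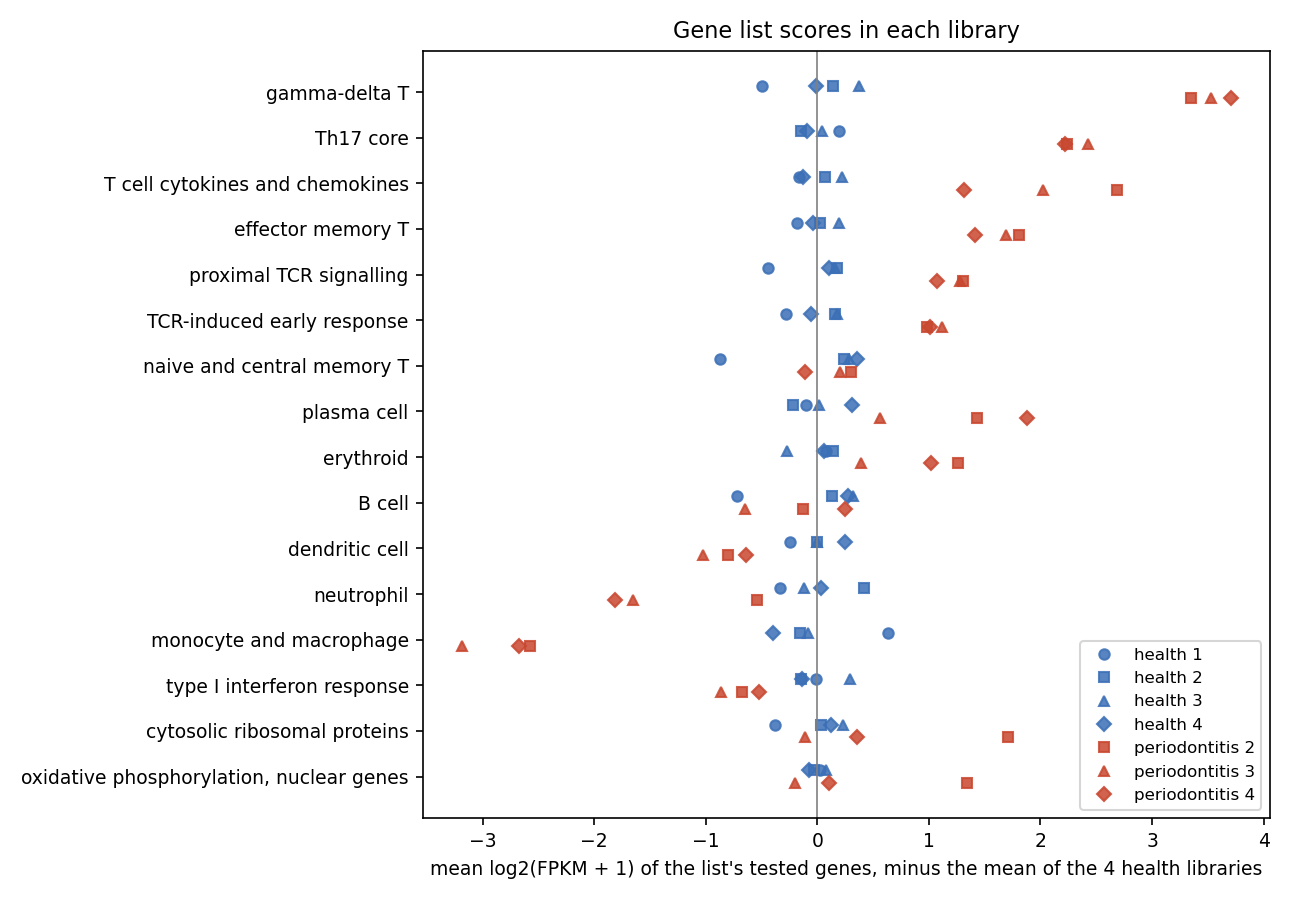
Mean log2(FPKM + 1) of the tested genes of 16 lists in each library, minus the mean of the 4 health libraries (horizontal axis); each mark is a library, blue for health and red for periodontitis. The gamma-delta T, Th17 and macrophage lists separate the groups with wide gaps, and the ribosomal and oxidative phosphorylation lists are highest in periodontitis 2.

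Genes of the type I interferon response were lower as a list, while most members did not pass. Of 29 tested members of the type I interferon list 7 were lower and 1 higher, or 8 and 1 over the list alone (camera adjusted p = 0.00102; adjusted p = 0.242 with an estimated correlation). Oas2, an antiviral sensor of double-stranded RNA, was 23.6 ± 8.63 FPKM in health and 2.26 ± 1.76 FPKM in periodontitis, and Ifit3 was 30.0 ± 10.1 and 6.24 ± 0.760 FPKM. In the same libraries the median log2 changes of the macrophage, neutrophil and dendritic cell lists were -3.35, -1.27 and -0.89. The exonuclease gene Isg20 was the higher interferon member, at a log2 fold change of 1.42. Ribosomal protein genes passed as a list (camera adjusted p = 2.05e-07) with 1 of 76 members past the threshold, Rpl24, and none over the list alone. Rpl24 lost its call without health 1, 2 or 4 or periodontitis 2 or 4 (adjusted p = 0.0719, 0.0664, 0.0750, 0.0569 and 0.0729; range 0.0111 to 0.170). The adjusted p of the list was 0.668 with an estimated correlation, and the mean score was 9.53 in periodontitis 2 and 7.72 and 8.18 in periodontitis 3 and 4, against 7.44 to 8.05 in health. Nuclear genes of oxidative phosphorylation passed as a list with 0 of 49 members past the threshold (camera adjusted p = 0.000547; adjusted p = 0.696 with an estimated correlation). Without periodontitis 2 the mean log2 value of this list was -0.06 (camera adjusted p = 0.939; range 5.87e-08 to 0.939). In that library the shortest protein-coding genes stood above the other periodontitis libraries by a median of 1.48 on the log2 scale, while the longest stood at -0.25.

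Over all 33 lists with at least 3 tested members, 17 were higher and 4 lower with the preset correlation, and the calls of the Th17 and effector memory lists held with an estimated correlation. At the level of libraries, the mean scores of 18 lists separated the groups fully (exact permutation p = 0.0571, two-sided, the smallest that 4 against 3 libraries can give), and the adjusted p of each over the 34 lists was 0.108.

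Genes tied to sex differed between the groups in every library. Xist, the transcript that silences an X chromosome in female cells, was 63.6 ± 8.48 FPKM in health and 0.640 ± 0.634 FPKM in periodontitis. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads together in each health library and 2193, 4108 and 2428 reads in periodontitis 2, 3 and 4. Eif2s3y was 16.9 ± 3.12 FPKM in periodontitis, at least 1501-fold higher than 3 reads over the health libraries. Genes on the X and Y chromosomes were 2.97% of the genes called and 2.92% of those tested. Without them 710 genes were higher and 1279 lower. These counts do not bear on an effect of sex on genes of other chromosomes. No library carried the sex pattern of the other group, so sex and periodontitis cannot be told apart for any gene here.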

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

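The scale relative to CD3 genes, the comparisons with B cell genes, the sex-linked tests and the correlations of libraries with each group were chosen only after the results were seen.

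In 14 of 122 results tested, 1 of the 4 health libraries stood apart from the other 3 by Dixon's test, where chance gives about 1 in 20 for a single result. The members of all lists together would give 25 of 171. Many of the results move together, so these counts do not measure an excess over chance. Health 1 was the library that stood apart in 13 of the 14. Its mean score was 3.99 for the proximal T cell receptor list (others 4.54 to 4.61) and 3.57 for naive and central memory T cells (4.68 to 4.80). On the log2(FPKM + 1) scale it was high in Adap2 at 6.46 (others 5.23 to 5.42), Mrc1 at 8.78 (7.32 to 7.51), Vcam1 at 9.79 (8.45 to 8.53), Itgad at 8.93 (7.29 to 7.56), Sdc3 at 9.23 (7.78 to 7.94), Tmem26 at 6.24 (4.71 to 4.97) and Entpd1 at 6.10 (4.99 to 5.16). It was low in Cd247 at 2.69 (3.39 to 3.52), Capg at 4.97 (5.73 to 5.84), Cr2 at 3.14 (4.34 to 4.45) and Ighm at 8.72 (9.62 to 9.75). Health 3 stood apart in Cox6c, at 4.61 (others 4.31 to 4.36).

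Zap70 was higher in 3 of 3 periodontitis libraries than in any health library. Scaling of the libraries as the cause is argued against by its smallest log2 change over 6 other scalings, 2.38. What follows takes the RNA of the CD3 subunit genes per T cell as unchanged, which was not tested. On that basis a rise of Zap70 per T cell as the whole change is argued against by the upper 95% bound of its change relative to these genes. That bound was 0.88, and at most 1.06 with any 1 library left out. A larger share of T cells among the sorted cells may account for most of the change of Zap70. Relative to the CD3 subunit genes the difference was 0.25, with an interval of -0.37 to 0.88. It was 0.49 (-0.00782 to 0.99) without periodontitis 2 and 0.15 and 0.12 without periodontitis 3 and 4. A smaller rise per T cell within those intervals stays open, as does the effect of periodontitis on either. Lck, a member of the T cell receptor list, differed by -0.71 relative to the CD3 genes (95% interval -1.21 to -0.21). Another T cell gene as the reference could therefore give another value for Zap70.

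Macrophage genes were lower in 3 of 3 periodontitis libraries, in cells that a flow sort for GFP had selected. A lower share of T cells in health, filled up by all other cell types alike, is argued against: the median log2 change of B cell genes lay 3.13 above that of macrophage genes. Fewer macrophages or less of their RNA among the sorted cells of the periodontitis libraries is a candidate explanation, with a median log2 change of -3.35 over 17 markers; C1qa, among the most abundant, was 1751 FPKM in health and 193 in periodontitis. Of these markers Ccr2 is shared with effector T cells. How far this reflects the sort or the mice was not tested.

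Xist and the Y-linked genes marked all 4 health libraries as female in pattern and all 3 periodontitis libraries as male, so that 7 of 7 libraries carried the pattern of their group. A swap of 1 library of each group is argued against, since over genes outside the X and Y chromosomes 0 libraries correlated more with the other group than with their own (smallest margin 0.0574); an exchange of whole groups would leave these values as they are. Female mice in health and male mice in periodontitis is a candidate explanation. Sex and periodontitis then cannot be told apart for the autosomal genes, because no library has the sex of the other group; 2.97% of the genes called lay on the X or Y chromosome.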

How the results depend on the processing

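The scale relative to CD3 genes and the omission of X and Y genes, of features under 200 bases (with rescaling), of health 1 with periodontitis 2, and of single libraries from the ratios were chosen only after the data were seen. The cause of a changed value was not tested, except that leaving out libraries leaves fewer samples.

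Zap70 kept its direction and call in 25 settings; relative to the CD3 subunit genes, its change was 0.25 (adjusted p = 0.656) and that of Csf2 -0.45, which the pseudocount sets, since Csf2 had 0 reads in health, and which measures no change per T cell. That scale was first run over all genes, where 24 were higher and 12239 lower and 33 of 89 named genes took the other direction, since genes outside T cells fall on it by construction; it was then kept to the study's genes. The counts of higher and lower genes were 415 and 2692 with libraries rescaled to one total, and 1428 and 973 without short features and with each library brought back to its former total, 2 changes made together. Leaving out 1 library in turn gave 445 (health 2) to 879 (periodontitis 3) higher and 871 (health 2) to 1372 (periodontitis 3) lower. With health 1 and periodontitis 2 left out, the counts were 496 and 988. An estimated correlation left 2 of 21 list calls. The list of genes the study names and that of inhibitory receptors lost theirs at estimated correlations of -0.154 and -0.0877. Both lie below the preset 0.01, so a higher correlation between members does not account for these losses. Of 2211 values for named genes, 2056 kept direction and call, 126 lost the call, 28 gained it and 1 reversed; of 889 for lists, 794, 46, 15 and 34.

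With a replicate block by library-name numbers, 321 genes were higher and 657 lower, and with one by title numbers 297 and 669. The adjusted p of Zap70 was 0.00679 and 0.0148 in them, that of Hbb-bt 0.200 and 0.190, of Car2 0.0529 and 0.137, of Rpl24 0.183 and 0.113 and of S1pr1 0.0559 and 0.0715. Among the named genes 14 and 19 lost the call in the first and second block, and 75 and 70 stayed the same. Those that lost it in both include Nfkbia (0.0563 and 0.0560), Il2ra (0.0873 and 0.0706) and Ikzf2 (0.0587 and 0.0752). The labels do not say whether equal numbers mark a shared day, cage or litter. The deviations of same-numbered libraries correlated at -0.05, -0.02 and 0.04 by library name and at -0.05, 0.06 and -0.10 by title. With so few libraries these values cannot settle whether the libraries were paired. In the first block the naive T cell list had a mean of -0.16; in the second those of CD8 T, NK and interferon-gamma genes were -0.16, 0.0420 and -0.16. The B cell and MHC class II lists gained a call in the first block (camera adjusted p = 0.0178 and 0.0198), and the inhibitory receptor list lost its call there (0.0918). The heat shock list lost its call in the second (0.126).

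Each list that turned direction was past the threshold neither before nor after; the direction is relative to other genes in camera and to no change in fry, and mean log2 changes follow. NK genes gave -0.25 and -0.16 at pseudocounts 0.1 and 0.5, -0.14 with no filter, 0.0335 at 5 FPKM, 0.0303 with quantile normalization, -0.57 with one total, -0.10 with hemoglobin, immunoglobulin and mitochondrial genes removed and the rest rescaled, -0.14 over protein-coding genes and -0.35 in voom. Interferon-gamma genes gave -0.12 at 5 FPKM, -0.56 with one total, -0.10 with median-of-ratios scaling, -0.11 with quantile normalization and -0.10 in fry; platelet genes -0.0583 at 5 FPKM; CD8 T genes -0.76 with one total; naive T genes 0.13 in fry. Without 1 library in turn the means ran from -0.51 to 0.0420 for NK, -0.16 to -0.0243 for interferon-gamma, -0.70 to 0.15 for CD8 T and -0.42 to 0.0633 for B cell genes, the last lower without health 1.

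The correlation of Zap70 with Il17a and its alternatives were not run. At these depths a 2-fold change was mostly missed in the simulated data, and genes under 1 FPKM were not tested.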

Other observations

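The ratios to CD3 genes and of receptor chains, and the members named here, were chosen only after the results were seen.

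Inhibitory receptor genes passed as a list (camera adjusted p = 0.0302; adjusted p = 0.169 with an estimated correlation), with 5 of 11 members higher and 2 lower, also over the list alone. It did not pass in camera without health 1 (adjusted p = 0.0702). Over the settings the adjusted p ranged from 4.45e-05, in fry, which tests against no change, to 0.182. Tigit was 5.67 ± 3.62 FPKM in health and 66.6 ± 16.7 FPKM in periodontitis, and Nt5e, which encodes the ectoenzyme CD73, was higher by 1.81 on the log2 scale. Entpd1 and Cd244a, both also carried by myeloid cells, were lower by log2 values of -2.67 and -2.63. The list of non-pathogenic Th17 genes did not pass (camera adjusted p = 0.459). In it Ctla4, Il10 and Ikzf3 were higher and Il6st and Cd5l lower, the last a macrophage gene that fell from 532 ± 340 to 36.2 ± 7.80 FPKM.

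Genes of antigen presentation by MHC class II did not pass (camera adjusted p = 0.134), with H2-DMb1 lower among 10, but did without health 1 or periodontitis 2 (adjusted p = 0.0145 and 0.0276; range 0.000884 to 0.693). The NF-kB list did not pass (camera adjusted p = 0.230), with 3 of 19 members higher and 1 lower, and had an adjusted p of 0.0479 in fry (range 0.0479 to 0.588). Lists of CD8 T cells (adjusted p = 0.892), NK and innate lymphoid cells (0.999), platelets (0.553), glycolysis (0.292), p53 targets (0.205), mitochondrially encoded mRNAs (0.205) and the interferon-gamma response (0.999) did not pass in camera. Those of CD8 T cells and mitochondrially encoded mRNAs were lower with health 1 and periodontitis 2 left out (adjusted p = 0.0413 and 0.0154; ranges 0.0413 to 0.988 and 0.0154 to 0.768). The mitochondrial list was also lower with quantile normalization and with library weights (camera adjusted p = 0.0165 and 0.0253). The mean and median of the interferon-gamma response were -0.10 and -0.04 where its test pointed up. Stromal and endothelial genes had 2 tested members, neither past the threshold. Cell cycle genes passed (camera adjusted p = 0.0351; adjusted p = 0.668 with an estimated correlation) with 0 of 26 members past the threshold, and did not without health 3 or periodontitis 4 (adjusted p = 0.211 and 0.314; range 0.00255 to 0.668). Heat shock and unfolded protein genes passed (camera adjusted p = 0.0165; adjusted p = 0.584 with an estimated correlation) with Dnajb1 higher among 17, and did not without health 4 or periodontitis 4 (adjusted p = 0.118 in both; range 0.00163 to 0.584). With libraries rescaled to one total the mean changes of the cell cycle and heat shock lists were -0.24 and -0.02.

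Of the 35 splits of the 7 libraries into 4 and 3, the real one gave 2053 genes past the threshold and the highest other gave 4. So 1 of 35 was as large, the smallest share that 35 splits can give. The other splits mix libraries of both groups, which puts the group difference into the spread and lowers their counts. They therefore cannot exclude chance as the source of the count.

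Relative to the mean of the CD3 subunit genes in each library, Il17a differed by 4.51 (95% interval 1.95 to 7.07), Cxcr6 by 2.24 (0.97 to 3.51) and Ctla4 by 2.08 (0.65 to 3.5) on the log2 scale, each with separate groups (exact permutation p = 0.0571, the smallest possible, two-sided). Lck differed by -0.71 (-1.21 to -0.21; exact p = 0.0571). Il23r differed by 1.42 (-0.22 to 3.05; exact p = 0.114), and Cd4, Lat and Cd5 by -0.45, 0.14 and 0.33 (exact p = 0.514, 0.229 and 0.400). The ratio of Il17a in health 2 and health 4 is set by the pseudocount, since it had 0 reads there. The same holds for Il23r in health 4. In health 1, 2 and 3 Il23r stood at 0.460, 0.310 and 0.608 FPKM, below the pseudocount of 1, so its difference understates its change. The mean FPKM of Il23r was 60.7-fold higher in periodontitis, and those of the CD3 subunit genes were 5.28-fold to 7.56-fold higher. No adjustment was made over the 11 ratios run.

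Gamma-delta T cells may be a larger part of the T cells in the periodontitis libraries. The log2 ratio of gamma-delta to alpha-beta receptor chain genes was higher by 1.21 in periodontitis (95% interval 0.20 to 2.21; exact permutation p = 0.0571), in 3 of 3 libraries. Without periodontitis 4 it was 0.80 (0.14 to 1.46), and the interval reached below 0 without health 1, 2 or 4 or periodontitis 3 (lower ends -0.0936, -0.0889, -0.13 and -0.0983). Near-identical gamma chain segments can share reads, and the sex of the mice stays open here too.

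In cells sorted for a reporter of the IL-17 locus, Il17a had 94 reads over the 4 health libraries together and 0 FPKM in health 2 and health 4, beside 13841 reads in periodontitis.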
